A study of Bos taurus with 46 samples.

How the data were processed

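The series measured RNA of bovine conceptuses at day 25 on long-oligonucleotide arrays with 2 colours. The labels divide 46 arrays into 23 specimens, each hybridised in both dye orientations against a reference standard RNA. The groups were NT embryonic discs (6 specimens), AI embryonic discs (5), NT extraembryonic tissue (6) and AI extraembryonic tissue (6). NT stands for the clones of the series title, and the labels give every specimen as female. Replicates are separate specimens, some of which share a leading number (63A1 and 63A2, 187_1 and 187_2, 260_1 and 260_2). In extraembryonic tissue the labels write the last 4 of these with an M at the end (such as 187_1M), whose meaning is not stated, and the M is left off here.

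Per the labels' protocols, RNA was isolated with Trizol, 10 µg was reverse-transcribed from random primers with an amino-allyl nucleotide, and the cDNA was coupled to Cy5 or Cy3. Per the labels, the images came from a GenePix 4000B scanner and GenePix 6.0. The deposited values are log2 ratios per spot, and no label states their base, normalization, filters or direction. The base was taken from the value at which extreme ratios stop, and 133 spots at that limit were left out. Of these, 60 were on Cy5 arrays, all with positive ratios, and 73 on Cy3 arrays, all with negative ratios. The arrays of a specimen had a Pearson r above 0 in every case (0.209 to 0.540 in discs, 0.393 to 0.705 in extraembryonic tissue), so the deposited ratios are already turned the same way. By ranks (Spearman rho) the agreement was weaker. It ran from −0.0331 in NT disc 63A2 to 0.359 in discs, and from 0.289 to 0.648 in extraembryonic tissue. The deposited values are not centred. Array medians ran from −0.70 to −0.30 in discs labelled with Cy5, from 0.19 to 0.57 in discs labelled with Cy3, from −0.48 to 0.41 in extraembryonic tissue labelled with Cy5 and from −0.41 to −0.02 in extraembryonic tissue labelled with Cy3. No label states which normalization the authors used or how they turned the swaps. Specimen over reference is the likely direction, because genes of trophoblast secretory products are then higher in extraembryonic tissue than in discs.

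The table holds 27648 spots, which are 13824 oligonucleotides in adjacent duplicate. Duplicate spots correlated with a median r of 0.960 across arrays, against 0.0619 for neighbouring spots of different oligonucleotides. Missing spots numbered 803 to 3440 per array, 3.90% in discs and 6.93% in extraembryonic tissue. Array medians also drifted along the spot numbers, by a median range of 0.642 over 48 stretches of 576 spots. Brightness was not used here, so signal over background is unknown, and the number of arrays limits the precision.

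For the main values each array was centred on its median, duplicate spots were averaged, and the arrays of a specimen were averaged to 1 value where both had a value. A probe was tested where each of the 4 groups had at least 3 specimens with a value, which left 12822 probes. Gene symbols came from a table that pairs the series' probes with genes, and matching 8620 probes to current symbols by gene identifier changed 0 symbols. Of all 13824 probes, 8645 had 1 symbol, 105 had several and 5074 were not listed. Of the tested probes, 8441 had 1 symbol (7892 genes), 104 had several and 4277 were not listed, and probes without 1 symbol are given by probe number only.

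Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 4 groups in the same fit, with Benjamini-Hochberg adjustment over probes, an adjusted p under 0.05 as the threshold and no replicate block. The 5 comparisons were NT against AI in each tissue, the difference of these effects between tissues, and extraembryonic tissue against disc within AI and within NT. All are two-sided. Gene lists were tested on gene means with limma's camera (preset correlation 0.01, adjusted over 23 lists), with camera at an estimated correlation and limma's fry beside it. Counts over a list's members are given over all probes and, where they differ, adjusted over the list alone. The spread between specimens was tested by exact permutation of group labels, and the correlation of the NT effects by relabelling leading numbers in both tissues together. Pairs of specimens with the same leading number were left out of the spread. Figures were drawn with matplotlib 3.10.9.

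The 23 lists were placental secreted families, trophoblast regulators and keratins, steroid and prostaglandin synthesis, pluripotency and epiblast, gastrulation and neural, imprinted and XIST, primitive endoderm and yolk sac, blood and blood vessel cells, endometrium, interferon response, MHC class I and antigen processing, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, cell cycle and DNA replication, chromatin and DNA methylation, chaperones and ER stress, apoptosis and p53, cholesterol and fatty acid metabolism, extracellular matrix and mesenchyme, nutrient transporters, IGF and growth factor signalling, and cell adhesion and junctions. Some genes stand in more than 1 list, such as VEGFA.

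The design, the lists and the rule for named genes were fixed before the data were examined. The rule takes up to 12 risers and 12 fallers with 1 symbol, the largest log2 differences among probes that pass and have the same sign in each dye alone, with 1 probe per gene. Where fewer than 5 probes pass it takes the 5 smallest p as values. From each list it adds up to 4 members with the smallest p, and the same genes are given for the difference between tissues. Genes named beyond the rule were chosen after their values were seen.

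The tests were run on simulated data with 200 changed probes of 12822 and 10 simulations. Each probe first had the same spread in both tissues, averaged from the real specimens. For NT against AI, changes of 0.5, 1 and 2 log2 units were recovered in 37.5%, 85.4% and 98.0% of cases in extraembryonic tissue (5.45% false among calls) and in 34.6%, 84.3% and 98.0% in discs (4.58% false). For the difference between tissues the recovery was 10.9%, 61.3% and 95.3% (5.50% false). Between tissues it was 34.9%, 84.0% and 98.6% in AI (4.79% false), and 38.1%, 86.3% and 98.5% in NT (4.46% false). With a spread of its own for each tissue, 23.4% of the simulated disc calls were false, and sets with no change gave up to 8 disc calls. The false share was then 7.11% for NT against AI in extraembryonic tissue, where sets with no change gave up to 3 calls. It was 6.88% for the difference, 6.83% between tissues in AI and 6.76% in NT. A shift of 0.3 in the glycolysis and hypoxia list was called by camera with its preset correlation in 10 of 10 simulations in both tissues. Genes were simulated as independent there, while the estimated correlation of this list in the data was 0.241. The simulation therefore does not show how camera performs on correlated lists.

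The alternatives were the deposited values without centring, quantile normalization, centring in stretches of spots, capped spots kept, each dye alone, all arrays with dye and specimen block, probes filtered by completeness or by agreement of the swaps, specimens with a shared leading number averaged or blocked, the conceptus number as a block, a robust and trended prior, array weights, only the groups compared, other thresholds, other probes per gene, and each specimen left out. Centring in stretches, keeping capped spots, and leaving out NT disc 196, the AI numbers 83, 187_1 and 187_2, or AI extraembryonic 260_2 and 351, and turning the ratios for the shares of NT disc 196, were chosen after seeing the data. So were the deposited values for list calls, the spread and the correlation of NT effects, quantile normalization for the spread and that correlation, and shared leading numbers averaged for that correlation. The same holds for every alternative for the lists of the difference between tissues. For named genes and list medians it holds for the probe filters, other probes per gene, the prior, array weights and the conceptus block.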

Results

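Gene expression was profiled in embryonic discs and in extraembryonic tissue of day 25 cattle conceptuses, from NT pregnancies (the clones of the series title) and from AI pregnancies. There were 6 NT and 5 AI discs, and 6 NT and 6 AI extraembryonic specimens. All levels are log2 ratios to a common reference RNA, relative to each array's median, in the likely direction of specimen over reference. The tissues separated clearly: specimens correlated at 0.694 to 0.928 within discs, at 0.875 to 0.965 within extraembryonic tissue and at 0.380 to 0.829 between tissues. The upper end between tissues came from NT disc 196, and without it the highest correlation was 0.603.

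The series title asks whether clones differ from normal conceptuses in the trophoblast. In extraembryonic tissue, NT specimens had higher RNA for the angiogenic factor VEGFA (probe 24003), which averaged 1.38 ± 0.35 in NT and 0.45 ± 0.19 in AI (SD, n = 6 each), a 1.90-fold difference. PNPT1 (probe 19977), a mitochondrial exoribonuclease, was 2.22-fold higher, and ALPL, the tissue-nonspecific alkaline phosphatase, and IGF2BP2, which binds IGF2 mRNA, were 1.91-fold and 1.89-fold higher. The lower genes were led by ESRRA (probe 447), an orphan nuclear receptor of mitochondrial energy metabolism, with −2.24 log2 units (SE 0.43). It averaged 2.38 ± 1.18 in AI and 0.14 ± 0.18 in NT (SD, n = 6 each). AI 351 was at 0.14, within the NT range of −0.19 to 0.31, and the other AI specimens were at 2.22 to 3.49. AI disc 351 was at 0.03, beside 1.06 to 2.84 in the other AI discs. MGAT1 (probe 23777), which starts the synthesis of complex N-glycans, averaged 0.69 ± 0.57 in AI and −0.91 ± 0.49 in NT (SD, n = 6 each). SIVA1 (probe 25035), a pro-apoptotic p53 target, averaged 0.64 ± 0.41 in AI and −0.58 ± 0.19 in NT (SD, n = 6 each).

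In all, 61 of 12822 probes passed limma's test in extraembryonic tissue, 43 higher and 18 lower in NT. Of these, 34 carried the symbol of a gene and 27 had no symbol. Their median absolute difference was 0.88 log2 units, with a range from 0.47 to 2.24. At an unadjusted p under 0.05 there were 1209 probes, against 641.1 expected by chance. All 61 had the same sign in each dye alone. The deposited values without centring gave 64 higher and 10 lower, with a median shift of 0.11 over all probes. With Cy5 only 20 were higher and 21 lower, with Cy3 only 17 and 5, and with shared leading numbers averaged 28 and 12.

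Among the other genes that rose were OTOS (1.11, SE 0.20), ZNF79 (1.09, SE 0.19), MOSPD2 (1.05, SE 0.21) and CD79B, a chain of the B-cell receptor (0.91, SE 0.17). BORCS5, a subunit of a complex that positions lysosomes, rose by 1.06 (SE 0.19, adjusted p = 0.00462). VPS18, part of the lysosomal tethering complexes, rose by 0.94 (adjusted p = 1.34e-04), and ZSWIM8, a ubiquitin ligase substrate receptor, by 0.88 (adjusted p = 1.06e-04). SLC22A8, an organic anion transporter, rose by 0.91 (adjusted p = 0.0484). Beyond the rule, SMAD1, which carries BMP signals, rose by 0.62, and the sialyltransferase ST6GALNAC6 also rose by 0.62. These genes were picked after their values were seen, and other called genes rose more, such as BAHCC1 and PATZ1 (0.82 each). The fucosyltransferases FUT9 and FUT6 fell by 1.12 each (adjusted p = 0.00805 and 6.14e-04). FUT9 had a value in only 4 of the 6 NT specimens, and its difference was −0.43 with Cy5 and −1.53 with Cy3. KIF23, a kinesin of the central spindle, fell by 0.78, and TLR4, the endotoxin receptor, fell by 0.75. LXN, a carboxypeptidase inhibitor, fell by 0.75, LRRC47 fell by 0.70, and LOC515578 fell by 0.79.

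Few of the called genes stood in the fixed lists. In the glycolysis and hypoxia list, 1 of 27 members rose (VEGFA, adjusted p = 0.00133) and 26 did not pass, while 20 of 27 lay above 0. HIF1A was at 0.47, CA9 at 0.35 and PGK1 at 0.35 (0.08 to 0.25 at its other probes), and adjusted over the list alone 2 rose. The cell cycle and DNA replication list had 1 riser among 41 members, RRM2, a subunit of ribonucleotide reductase (0.69, SE 0.14), and CDC6 was at −0.75 (adjusted p = 0.0928). Adjusted over the list alone, 1 rose and 1 fell there. In the IGF and growth factor list VEGFA rose and 36 of 37 members did not pass, with TGFB3 at −0.93 (adjusted p = 0.13), IGF2R at −0.72 and INSR at 0.40 (0.71 at its other probe). Adjusted over the list alone, 2 rose and 1 fell.

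No member of the other 20 lists passed. In the interferon response list EIF2AK2 was at 0.64 (adjusted p = 0.0605) and IFI6 at 0.57, and adjusted over the list alone 1 rose. Of the placental secreted genes, CSH2 was at 0.64 (−0.01 with Cy5 only), IFNT2 at 0.46 and PAG20 at −0.48, and 3 of 20 lay above 0. Of the trophoblast regulators TFAP2C was at −0.41 and HAND1 at −0.31. AKR1B1, an aldo-keto reductase, was at −0.85 and HPGD, which degrades prostaglandins, at 0.50. HNF4A was at 1.26 (0.04 at its other probe) and FGG at 1.11 in the primitive endoderm and yolk sac list, of which 16 of 22 members lay above 0. RPS3 was at −0.81, HADHB, of mitochondrial fatty acid oxidation, at −0.60, PLIN2, a lipid droplet protein, at −0.80 (−0.40 at its other probe) and COL6A3 at −0.77.

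No list passed limma's camera test (smallest adjusted p = 0.273, glycolysis and hypoxia, higher, median 0.08), while 1 of the 23 lists had an unadjusted p under 0.05. The smallest adjusted p was 0.979 with an estimated correlation and 0.856 with fry. The median and the test differed in sign for oxidative phosphorylation (0.01, lower) and for IGF signalling (−0.02, higher), and the means of the ribosomal list (−0.03) and the cell cycle list (−0.0023) lay below 0 beside medians of 0.03. The list count was 1 without NT 63 or AI 260_1 and 2 without AI 187_2.

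XIST, the RNA that silences an X chromosome, was low in 3 of the 6 AI extraembryonic specimens (−3.66 to −0.95, against 1.64 to 2.59 in the 8 other specimens with a value), and its NT minus AI difference of 2.34 did not pass. Every NT specimen with a value was high, so XIST status is not balanced between NT and AI. Without these 3 numbers in both tissues 17 probes passed in extraembryonic tissue (7 higher, 10 lower), 14 of them among the 61. Leaving out 3 AI specimens of extraembryonic tissue alone gave 19 calls for these 3 and 12 to 57 for the other sets of 3 (median of all 20 sets 27). Without these 3 numbers in both tissues all 61 kept their sign, which could not turn in the 46 whose NT and AI specimens did not overlap. Their median size was 0.83 with a median SE of 0.182, against 0.88 and 0.154 in the full set. VEGFA was then at 0.84 (adjusted p = 0.0846) and ESRRA at −1.85 (adjusted p = 0.112), while PNPT1, MGAT1, SIVA1 and FUT6 still passed. The primitive endoderm and yolk sac list then lay higher in NT (median 0.59, adjusted p = 1.84e-05, and adjusted p = 0.903 with an estimated correlation), the only list that passed. AI specimens 260_2 and 351 stood apart in this list, with means of 0.91 and 0.82 beside 1.80 to 2.84 in the other 10 extraembryonic specimens. Its member AFP was at 2.56 and 2.42 in them, beside 4.26 to 6.95. With only these 2 specimens left out the list median was −0.16 (adjusted p = 0.239), and 61 probes passed in extraembryonic tissue.

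**Figure D1:**
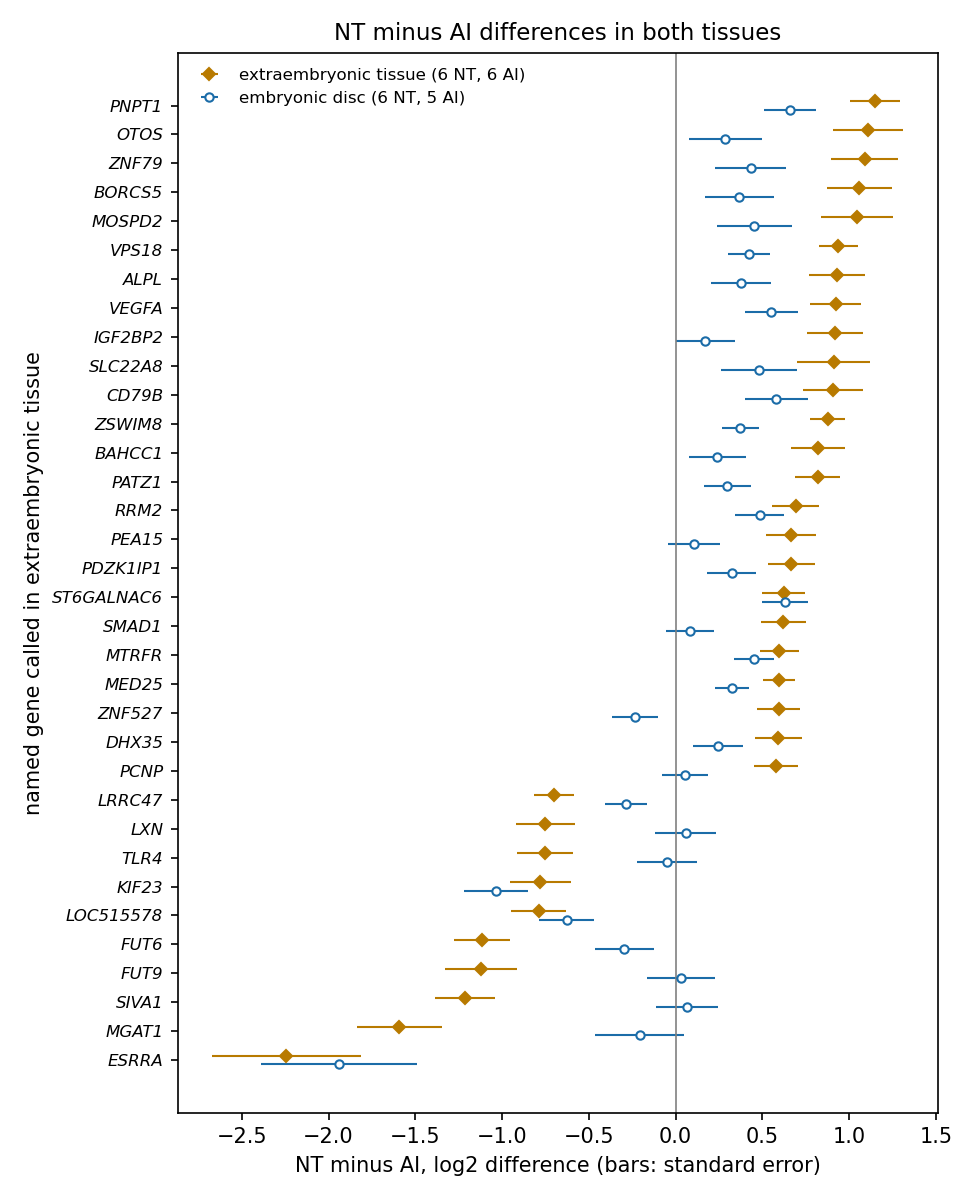
NT minus AI difference (log2 units, x axis; bars, standard error) of the 34 named genes that passed in extraembryonic tissue (y axis), with extraembryonic tissue as filled diamonds (6 NT, 6 AI) and discs as open circles (6 NT, 5 AI). ESRRA is the lowest in both tissues (−2.24, and −1.94 in discs, where it did not pass), and SIVA1 is low in extraembryonic tissue (−1.21) and at 0.07 in discs.

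The same question was asked of the embryonic discs. KIF23 (probe 6555), needed for the final step of cell division, averaged 0.01 ± 0.24 in AI discs (SD, n = 5) and −1.02 ± 0.14 in NT discs (SD, n = 6), so that it fell in both tissues. PIP4K2A (probe 1175), a phosphoinositide kinase, rose by 0.68 (SE 0.13; 0.29 at probe 22221, which did not pass), and PPT2 (probe 22247), a lysosomal thioesterase, rose by 0.61 (SE 0.11). The other 4 probes that passed carried no symbol and rose, led by probe 4677 at 1.46 (SE 0.20), which also rose in extraembryonic tissue by 0.90.

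In discs 7 of 12822 probes passed limma's test, 6 higher and 1 lower in NT, and 1127 had an unadjusted p under 0.05. All 7 had the same sign in each dye alone. The deposited values without centring gave 2 higher and 0 lower. The count was 2 without NT 63A1, NT 202 or AI 260_1, 3 without AI 187_1 or AI 351, and 4 without NT 196 or without the 3 AI numbers with low XIST. It was 1 with only the disc groups in the fit. Simulated discs with no change and their own spread gave up to 8 calls.

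Placental secreted genes as a list lay higher in NT discs: 20 of 20 members were above 0 with a median of 0.70 (camera adjusted p = 0.00216, and adjusted p = 0.990 with an estimated correlation). None of the 20 passed alone, with PAG17, a pregnancy-associated glycoprotein, at 1.26, TKDP4 at 1.23 and PRP1 at 0.67. NT disc 196 held a mean of 5.15 for this list, beside 0.27 to 1.62 in the other NT discs and 0.97 ± 0.40 in the AI discs (SD, n = 5). Without it the list median was −0.05 (adjusted p = 0.836). The primitive endoderm and yolk sac list lay lower in NT discs, with 5 of 22 members above 0 and a median of −0.35 (adjusted p = 0.00750, and adjusted p = 0.990 with an estimated correlation). None of its members passed alone, with FGG, a fibrinogen chain, at −1.19, MTTP, which loads lipoproteins, at −0.84, and APOM at −0.77. Without NT disc 196 its median was −0.46 (adjusted p = 0.00178, and adjusted p = 0.858 with an estimated correlation).

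**Figure D2:**
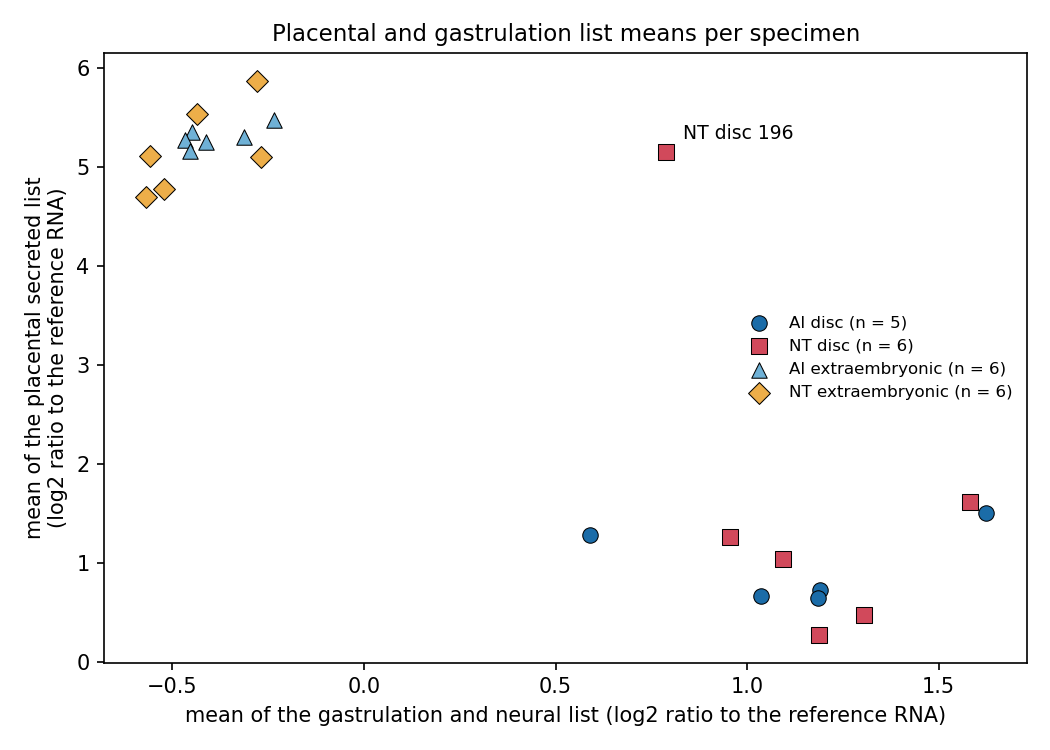
Mean of the placental secreted list (y axis) against the mean of the gastrulation and neural list (x axis), both as log2 ratios to the reference RNA, with a point for each specimen marked by group. NT disc 196 has a placental mean of 5.15, as in extraembryonic tissue (4.69 to 5.87), with a gastrulation mean of 0.79 in the range of the other discs.

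The other 21 lists did not pass in discs. VEGFA was at 0.55, BNIP3 at 0.66 (−0.21 at its other probe) and CA9 at 0.35 in the glycolysis and hypoxia list. TEK, an endothelial receptor, was at −0.77, TAP1, a peptide transporter for MHC class I, at 0.52, AKR1B1 at 1.14, PTGES, a prostaglandin synthase, at 0.38, IGF2 at −0.48, and H19 at −0.39. Adjusted over the list alone, 2 members rose in the steroid and prostaglandin list, 1 in the MHC list and 1 in the glycolysis list, and 1 fell in the blood list. NT disc 196 held AKR1B1 at 3.22, beside 0.25 to 1.42 in the other NT discs. Without it AKR1B1 was at 0.73, and adjusted over the list alone 0 rose in the steroid and prostaglandin list. XIST was at 3.76 (adjusted p = 0.35), with −2.82 to −1.82 in AI discs 83, 187_1 and 187_2 and 3.55 to 4.60 in the 7 other discs with a value. Median and test differed in sign for trophoblast regulators (0.03, lower), pluripotency (0.04, lower), blood (0.03, lower), endometrium (−0.09, higher), chaperones (−0.01, higher) and interferon response (0.00, lower). The imprinted list (test lower) had a mean of 0.17 beside a median of −0.00, and the chromatin list (test lower) a mean of 0.01. The list count was 0 without AI 187_1, 1 without NT 63A2, NT 196 or AI 351, and 5 without AI 187_2 or without the 3 AI numbers with low XIST.

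**Figure D3:**
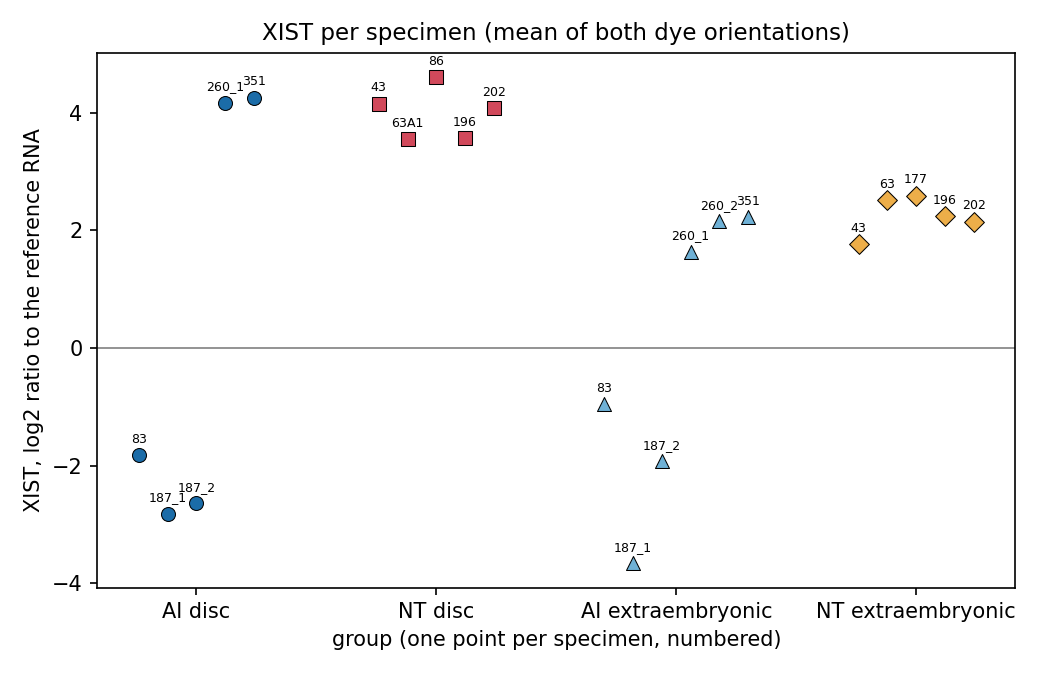
XIST (log2 ratio to the reference RNA, y axis) in each specimen with a value, by group (x axis), with the numbers of the labels less the M that 4 of them carry. AI numbers 83, 187_1 and 187_2 lie from −3.66 to −0.95 in extraembryonic tissue and from −2.82 to −1.82 in discs, and the others lie above 1.6.

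The test of the difference asks whether the NT effect itself differed between tissues. SIVA1 had the smallest p: its effect was −1.21 in extraembryonic tissue and 0.07 in discs, a difference of −1.28 (SE 0.25, adjusted p = 0.187). ZNF527, a zinc finger gene, had 0.59 and −0.23, a difference of 0.83 (adjusted p = 0.276), and MGAT1 had a difference of −1.38 (adjusted p = 0.440). KIF23 passed in both tissues (difference 0.25). ESRRA passed in extraembryonic tissue only and was at −1.94 in discs (adjusted p = 0.111, difference −0.30). The 3 further probes with the smallest p carry no symbol, with −1.38 for probe 4185, −0.84 for probe 22973 and 1.01 for probe 23893.

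No probe passed limma's test of the difference, and 949 had an unadjusted p under 0.05. The count was 1 without AI disc 351 and 2 without NT extraembryonic 86. Of the 61 probes called in extraembryonic tissue, 55 had the same sign in discs, with a median disc difference of 0.32 in that direction. The tissues shared 4 called probes, 3 higher and 1 lower in both, where 0.0201 and 0.00140 were expected from independent lists. The lists are not independent, since conceptus numbers occur in both tissues and the fit shares each probe's spread. These expected counts are therefore no test of a shared NT effect. Across the 12822 probes, which are not independent replicates, the NT effects of the tissues correlated with r = 0.110 and rho = 0.0646 (permutation p = 0.362 over 210 relabellings).

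Among the lists, the placental secreted families had a lower NT effect in extraembryonic tissue than in discs (median −0.96, 2 of 20 above 0, adjusted p = 0.00173). The primitive endoderm and yolk sac list had a higher effect (0.64, 18 of 22 above 0, adjusted p = 0.00173), and the apoptosis and p53 list a lower effect (−0.13, 5 of 24 above 0, adjusted p = 0.0452). No member passed, and each list had an adjusted p of 0.902 with an estimated correlation. Without NT disc 196 the placental difference was −0.13 (adjusted p = 0.475), and only the primitive endoderm list passed (0.69, adjusted p = 3.70e-04, and adjusted p = 0.913 with an estimated correlation). Without AI extraembryonic 260_2 and 351 the primitive endoderm difference was 0.17 (adjusted p = 0.753), and only the placental list passed (−0.98, adjusted p = 0.00434, and adjusted p = 0.917 with an estimated correlation). The list count was 5 without AI disc 187_2 and 1 without AI extraembryonic 260_2. Median and test differed in sign for trophoblast regulators (0.03, lower), MHC class I (0.02, lower), chaperones (0.02, lower) and cell adhesion (0.02, lower), and the mean was −0.06 beside a median of 0.02 for the imprinted list and −0.05 for the trophoblast regulators.

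NT and AI specimens were also compared for how much they differed among themselves. The mean distance between specimens (1 minus Pearson r) was 0.171 among NT discs and 0.179 among AI discs, a difference of −0.00733 (exact permutation p = 0.855 over 462 splits). In extraembryonic tissue it was 0.0670 in NT and 0.0768 in AI, a difference of −0.00977 (exact permutation p = 0.439 over 924 splits).

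Within AI pregnancies the tissues differed in genes of the trophoblast and of the embryo proper. The pregnancy-associated glycoproteins PAG5, PAG9, PAG17, PAG7, PAG8 and PAG20, secreted by trophoblast, were higher in extraembryonic tissue by 5.42 to 6.03 log2 units (other probes of PAG7 and PAG17 gave 5.08 to 7.14), and the trophoblast Kunitz domain protein TKDP1 by 5.40. DHRS9 (probe 12737), a retinol dehydrogenase, averaged 6.21 ± 0.39 in extraembryonic tissue (SD, n = 6) and −0.27 ± 0.16 in discs (SD, n = 5). The genes that were lower included the Wnt antagonist SFRP1 (−4.01, SE 0.44), the protocadherin PCDH18 (−3.95, SE 0.34), and the HOX cofactors MEIS1 (−3.37) and MEIS2 (−3.34).

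In AI, 7366 probes passed limma's test, 3683 higher and 3683 lower in extraembryonic tissue, and 5637 of them had the same sign in each dye alone. They stood for 4675 genes, and 467 probes differed by over 2 log2 units. The deposited values without centring gave 2661 higher and 4048 lower, with a median shift of −0.10 over all probes. Further genes that rose were CPA5, a carboxypeptidase (5.85), POLR2H, a shared RNA polymerase subunit (5.67, SE 0.16, adjusted p = 4.46e-18), TMEM139 (5.66), and LCP1, an actin-bundling protein (5.63). Further genes that fell were MSANTD3 (−3.94), the chemokine CXCL14 (−3.74), SPARCL1 (−3.59), the endothelin receptor EDNRA (−3.42), CA3 (−3.29), TF, which encodes transferrin (−3.22), CRABP1, a retinoic acid binding protein (−3.14), and the axon guidance receptor ROBO1 (−3.14).

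Of the placental secreted list, 18 of 20 members rose and 0 fell (median 5.30, adjusted p = 1.13e-08, and adjusted p = 0.229 with an estimated correlation). The likely direction of the ratios was taken from such genes, so the sign of this list between tissues, in AI and in NT, is not a separate result. Of the trophoblast regulators and keratins, 10 rose and 1 fell among 17 (median 0.78, adjusted p = 0.00373, and adjusted p = 0.152 with an estimated correlation), with GATA2 at 2.42, HAND1 at 2.15 and TFAP2C at 2.14. The gastrulation and neural list was the mirror of these, with 2 risers and 14 fallers among 17 (median −1.55, adjusted p = 1.63e-05, and adjusted p = 0.152 with an estimated correlation). TWIST1, a mesoderm regulator, fell by 3.09, STMN1, a microtubule regulator, by 2.55, and the growth factor MDK by 2.04. Cell cycle genes were lower, with 5 risers and 26 fallers among 41 (median −0.67, adjusted p = 7.90e-05, and adjusted p = 0.178 with an estimated correlation), among them TOP2A (−2.15) and CCNE1 (−1.94). Ribosomal protein genes were lower too, with 1 riser and 34 fallers among 58 (median −0.51, adjusted p = 5.19e-05, and adjusted p = 0.501 with an estimated correlation), such as RPL9 (−1.21) and RPL22 (−1.16).

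Cell adhesion genes had 19 risers and 6 fallers among 39 (median 0.24, adjusted p = 0.00845, and adjusted p = 0.504 with an estimated correlation), led by the gap junction gene GJB2 (4.15) and LGALS3 (3.74). Extracellular matrix genes had 17 risers and 6 fallers among 38 (median 0.43, adjusted p = 0.0499, and adjusted p = 0.661 with an estimated correlation), with TIMP2 at 2.99 (0.34 at its other probe) and COL6A1 at 1.80. Apoptosis and p53 genes had 14 risers and 4 fallers among 24 (median 0.54, adjusted p = 0.0115, and adjusted p = 0.269 with an estimated correlation), among them CFLAR, which blocks caspase activation (2.13, and 1.39 at its other probe). Blood and vessel genes had 1 riser and 11 fallers among 18 (median −0.86, adjusted p = 0.00449, and adjusted p = 0.152 with an estimated correlation), such as CD74 (−1.93) and the globin HBQ1 (−1.64). Chromatin genes had 4 risers and 16 fallers among 33 (median −0.32, adjusted p = 0.00696, and adjusted p = 0.152 with an estimated correlation), led by the histone deacetylase HDAC2 (−2.24). Primitive endoderm and yolk sac genes had 1 riser and 12 fallers among 22 (median −1.27, adjusted p = 0.0298, and adjusted p = 0.661 with an estimated correlation), with MTTP at −2.15, ALB at −1.56 and CLDN6 at 1.72. Without AI extraembryonic 260_2 and 351 its median was −0.70 (adjusted p = 0.139).

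These 11 lists passed in AI, and 0 passed with an estimated correlation. With fry, which does not compare a list with the other genes, the primitive endoderm list had an adjusted p of 0.0566. Among the rest of the 11 lists the largest was 5.96e-04. Fry also gave small values for lists that camera did not call, such as imprinted and XIST (adjusted p = 9.18e-07). Without NT disc 196, which shares the fit, the placental and trophoblast lists passed in AI with an estimated correlation (adjusted p = 0.0431 each). Adjusted over the list alone, the counts above were the same except for gastrulation (15 fell), blood (13 fell) and cell cycle (6 rose, 27 fell).

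Within NT pregnancies the tissues differed in much the same genes. DHRS9 was higher in extraembryonic tissue by 5.45 (SE 0.52), CPA5 by 5.56 (SE 0.64), and PAG5 by 4.97 (SE 0.68). NT disc 196, with its placental mean of 5.15 beside 0.27 to 1.62 in the other NT discs, lowers such values, and without it PAG5 was at 6.10 (SE 0.23) and DHRS9 at 6.21. The vasodilator ADM was higher by 4.56 (SE 0.59) and the proteoglycan SRGN by 4.52 (SE 0.68). CA3, a carbonic anhydrase, fell by 4.47 (SE 0.53), SFRP1 by 4.45 (SE 0.53) and TWIST1 by 3.58 (SE 0.29).

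In NT, 7454 probes passed limma's test, 3753 higher and 3701 lower, for 4754 genes, and 410 probes differed by over 2 log2 units. Of the 7454, 5516 had the same sign in each dye alone. AI and NT shared 6070 called probes, of which 6068 had the same sign, where 1078 higher and 1063 lower were expected from independent lists. The fit shares each probe's spread, so these lists are not fully independent. Across probes the tissue differences of AI and NT correlated with r = 0.936 and rho = 0.915. Other genes that rose were POLR2H (5.10, SE 0.15), LCP1 (4.98), PAG8 (4.87), PAG9 (4.66), PAG20 (4.61), PAG14 (4.59) and GCA, a calcium-binding protein (4.48). Other genes that fell were MSANTD3 (−4.22), PCDH18 (−4.10), MEIS1 (−3.57), CRABP1 (−3.56), the platelet chemokine PF4 (−3.52), AIF1L (−3.52, and −1.06 at its other probe), ROBO1 (−3.38), the tubulin TUBA1A (−3.31) and CXCL14 (−3.27).

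In NT 8 lists passed. The placental secreted list had 19 risers and 0 fallers among 20 (median 3.98, adjusted p = 1.19e-06, and adjusted p = 0.365 with an estimated correlation), and without NT disc 196 its median was 4.85 (adjusted p = 3.25e-14, and adjusted p = 0.0502 with an estimated correlation). The trophoblast regulators had 9 and 1 among 17 (median 0.83, adjusted p = 0.00404, and adjusted p = 0.170 with an estimated correlation), with HAND1 at 2.37 and CDX2 at 1.91. Cell adhesion genes had 21 risers and 5 fallers among 39 (median 0.47, adjusted p = 0.00783, and adjusted p = 0.497 with an estimated correlation), with GJB2 at 3.61 and E-cadherin, CDH1, at 2.58. The gastrulation and neural list had 2 and 15 among 17 (median −1.77, adjusted p = 2.96e-06, and adjusted p = 0.170 with an estimated correlation). The ribosomal list had 1 and 38 among 58 (median −0.47, adjusted p = 2.66e-06, and adjusted p = 0.400 with an estimated correlation), and the cell cycle list 4 and 30 among 41 (median −0.56, adjusted p = 2.96e-06, and adjusted p = 0.170 with an estimated correlation), with CKS2 at −2.25. The blood list had 1 and 12 among 18 (median −0.66, adjusted p = 0.00783, and adjusted p = 0.170 with an estimated correlation) and the chromatin list 4 and 13 among 33 (median −0.22, adjusted p = 0.0208, and adjusted p = 0.170 with an estimated correlation), with HDAC2 at −2.69. With an estimated correlation 0 passed. With fry the largest adjusted p among these 8 lists was 1.17e-04, and the imprinted and XIST list, which camera did not call, had 3.46e-06. Adjusted over the list alone, the counts were the same except for the ribosomal list (2 rose, 39 fell) and the cell cycle list (4 rose, 31 fell).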

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

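All tests of the pattern in NT disc 196 were chosen after the result was seen. A search for specimens far from the rest of their group found 12 values in 162 groups tested, where 8.1 are expected by chance, and 3 lists differed in their NT effect between tissues.

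NT disc 196 had a mean correlation of 0.752 with the other discs and of 0.788 with extraembryonic specimens, and its placental secreted list averaged 5.15. Extraembryonic tissue carried into the disc sample stays open: the share of extraembryonic RNA was 0.648 (interquartile range 0.396 to 0.943) from 108 probes high in extraembryonic tissue and 0.354 (0.175 to 0.489) from 200 probes high in discs, a difference of 0.294. In the other discs the first share ran from −0.0144 to 0.00931 and the second from −0.376 to 0.336, so both shares of NT disc 196 are the highest of the discs, the second by little. With every ratio turned they were 0.976 (others −0.269 to 0.247) and 0.0697 (others −0.0594 to 0.0593). A sample exchanged for an extraembryonic specimen is argued against, since its highest correlation with such a specimen was 0.829 and the lowest within that tissue was 0.875. Poor arrays are argued against by Pearson r only, which was 0.421 between its swapped arrays, beside a median of 0.392 in the other discs. By ranks its swapped arrays had a rho of 0.126, and the other discs ran from −0.0331 to 0.359.

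The NT effect differed between tissues for the placental secreted list (adjusted p = 0.00173), the primitive endoderm and yolk sac list (adjusted p = 0.00173) and the apoptosis and p53 list (adjusted p = 0.0452), each with adjusted p = 0.902 with an estimated correlation. Without NT disc 196 the placental difference was −0.13 (adjusted p = 0.475), and without AI extraembryonic 260_2 and 351 the primitive endoderm difference was 0.17 (adjusted p = 0.753). AI disc 187_2 had a mean correlation of 0.779 with the other discs. Its extracellular matrix list averaged 1.83, and probe 4677 was at −0.13. AI extraembryonic 351 had a mean of 1.34 for the trophoblast regulators and keratins. AI extraembryonic 83 had a mean of −0.22 for the interferon response list. NT extraembryonic 86 had means of 0.39 for the chaperone list and 0.38 for the apoptosis list. OTOS was at 0.46 in NT extraembryonic 196, and KIF23 was at 0.42 in AI disc 260_1.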

How the results depend on the processing

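Of 248 results of named genes that passed, the direction was kept in every setting but for 7 between tissues, each in 1 dye alone, and the cause was not tested. The named risers and fallers were chosen for the same sign in each dye, so for them the settings with 1 dye are no test of direction. Among all tissue calls, 5637 of 7366 in AI and 5516 of 7454 in NT had the same sign in each dye alone. Of 205 that did not pass, 18 had the other sign in at least 1 setting, such as CSH2 in extraembryonic tissue (−0.0116 with Cy5 only) and SLC1A5 there (−0.68, and 0.40 with Cy3 only). With Cy3 only the 7 were HPGD at 0.34 and COX4I1 at −0.0057 in AI, and HSD3B1 at −0.33, LPL at 0.0802 and LSS at 0.37 in NT. With Cy5 only they were IFI6 at 0.0661 in AI and PGR at 0.18 in NT. The 61 calls in extraembryonic tissue became 97 with centring in stretches of spots, 22 with Cy3 only, 40 with shared leading numbers averaged, 17 without AI 83, 187_1 and 187_2, 143 with all arrays and a specimen block, 338 with array weights and 37 at an adjusted p under 0.01. The specimen block had a correlation of −0.140, so the 2 dyes of a specimen counted as more than independent replicates, and its counts are not relied on. The 7 disc calls became 2 with values as deposited, 2 with Cy5 only, 1 with Cy3 only, 3 with shared leading numbers averaged, 4 without the 3 AI numbers, 14 with probes on all arrays, 37 with all arrays and a specimen block, 14 with a robust and trended prior, 3 with array weights, 1 at an adjusted p under 0.01 and 1 with only the groups compared. The difference had 18 calls with all arrays and a specimen block. Tissue calls became 3746 in AI and 3716 in NT with the best-agreeing probes, and 4757 and 4624 at 1.5-fold, where fewer probes can pass. List calls in extraembryonic tissue became 2 with shared leading numbers averaged and 1 without the 3 AI numbers, and in discs 5 without them. Between tissues they became 6 in AI with Cy3 only and 5 in NT with Cy5 only. For the difference, list calls became 1 without AI extraembryonic 260_2 and 351. With an estimated correlation 0 lists passed in any comparison of the full set, and 2 in AI without NT disc 196. The smallest adjusted p with fry was 0.856 for NT against AI in extraembryonic tissue, 0.897 in discs and 0.985 for the difference. Without each specimen in turn, calls ran from 44 to 83 in extraembryonic tissue, from 2 to 10 in discs, from 0 to 2 for the difference, from 6842 to 7385 between tissues in AI and from 7001 to 7632 in NT. List calls ran from 0 to 2, 0 to 5, 1 to 5, 9 to 11 and 8 to 9 in the same order. The spread difference ran from −0.0417 to 0.0255 in discs and from −0.0196 to −0.00264 in extraembryonic tissue, and the correlation of NT effects from 0.0495 to 0.158. That correlation was −0.00549 with Cy5 only, 0.183 with shared leading numbers averaged and 0.167 without AI extraembryonic 260_2 and 351. Signal over background is unknown, so its limit cannot be given. Causes other than the stated ones were not tested.

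With the conceptus number as a replicate block, the difference had 0 calls, and the tissues differed in 6513 probes in AI and 5139 in NT. Of 9 pairs with the same number in both tissues, only 1 correlated best with its own number.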

Other observations

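Some lists that did not pass between tissues held members that changed. In the imprinted and XIST list, 1 of 20 members rose and 9 fell in AI (median −0.40, adjusted p = 0.0673), and 3 rose and 8 fell in NT (median −0.36, adjusted p = 0.102). PHLDA2, which restrains placental growth, was higher in extraembryonic tissue by 2.62 in AI (0.33 at its other probe), and PLAGL1 and NNAT fell by 2.65 and 2.33. In the MHC class I list, 8 of 18 rose and 1 fell in AI (median 0.21, adjusted p = 0.103), with CALR at 1.44 and TAPBP at 1.25, and 9 rose and 1 fell in NT (median 0.30, adjusted p = 0.0940; adjusted over the list alone, 8 and 1). In the interferon list, 7 of 22 rose and 4 fell in AI (median 0.16, adjusted p = 0.579; adjusted over the list alone, 7 and 3), and 9 and 1 in NT (0.26, 0.162). Steroid and prostaglandin genes had 5 risers and 2 fallers of 13 in AI (0.22, 0.213) and 7 and 1 in NT (0.50, 0.261), with CYP11A1, which makes pregnenolone, at 2.22 in AI and PTGS2 at 2.38 (probe 19715) and 5.51 (probe 21731).

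Nutrient transporters had 9 risers and 6 fallers of 24 in AI (median 0.18, adjusted p = 0.650), with SLC1A3 at 1.94 and SLC7A5 at −1.30 (0.47 at its other probe), and 7 and 7 in NT (0.10, test lower, 0.982). Glycolysis and hypoxia genes had 7 risers and 10 fallers of 27 in AI (−0.22, 0.650), with ADM at 5.32 and PFKM at −1.77, and 8 and 9 in NT (−0.08, 0.905). IGF signalling had 10 and 9 of 37 in AI (−0.03, test higher, 0.799) and 10 and 7 in NT (0.12, 0.526), with TGFB1 at 2.22 in AI and VEGFC at −2.32. Chaperones had 14 and 12 of 35 in both (AI 0.13, 0.875; NT 0.27, test lower, 0.978), and cholesterol genes 13 and 10 of 34 in AI (0.05, 0.875) and 11 and 10 in NT (−0.03, 0.930), with FASN at 1.56 in AI (0.01 at its other probe). Oxidative phosphorylation had 13 and 11 of 75 in AI (0.02, 0.875) and 9 and 18 in NT (−0.05, 0.680). In AI the means of the oxidative phosphorylation (−0.0074) and cholesterol (−0.0070) lists lay below 0, while their tests were higher. Endometrium genes had 5 and 3 of 12 in AI (0.23, 0.650) and 5 and 2 in NT (0.25, 0.461), and pluripotency genes 2 and 2 of 6 in AI (−0.01, 0.741) and 1 and 2 in NT (−0.32, 0.461), with SOX2 at −1.45 in AI. In NT the apoptosis list had 12 and 5 of 24 (0.36, 0.135), extracellular matrix 13 and 4 of 38 (0.31, 0.0651) and primitive endoderm 2 and 8 of 22 (−0.35, 0.461). Adjusted over the list alone, the counts differed in AI for oxidative phosphorylation (9 rose, 8 fell) and chaperones (15 and 13), and in NT for oxidative phosphorylation (8 and 13), chaperones (16 and 12), glycolysis (8 and 10) and primitive endoderm (1 and 7).

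Of the tests below, those of an array fault, of the sets of AI specimens left out, of the standard errors and of the effect in a single tissue were chosen after the result was seen. XIST was low in AI 83, 187_1 and 187_2 in both tissues, although the labels call them female. An array fault is argued against, since all 12 arrays lay below every other specimen in the same dye. Male conceptuses fit the test on 10 genes that escape X inactivation, whose mean lay below the median of the other specimens in 6 of 6 cases, but 4 other specimens per tissue also lay below the highest of the 3. XIST itself was at least 5.37 log2 units below every other disc with a value, and at least 2.59 below in extraembryonic tissue. If the 3 are male, sex is confounded in part with NT against AI, because every NT specimen with a value had high XIST. Whether AI 83, 187_1 and 187_2 set the number of extraembryonic calls stays open. Leaving them out of extraembryonic tissue gave 19 calls, rank 3 from the fewest among 20 sets of 3 AI specimens (median of all sets 27, other sets 12 to 57). Whether they alone made the 61 differences is not decided by leaving them out. Without them in both tissues all 61 kept their sign, but NT and AI specimens did not overlap in 46 of the 61, whose sign could not turn. Of the 61, 14 still passed. The median difference was 0.83 (median SE 0.182), beside 0.88 (0.154) in the full set, so the other AI specimens also differed from NT at these probes. The 61 were chosen in the full set, so part of this size is kept by the choice.

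More probes passed in extraembryonic tissue than in discs. A larger disc spread stays open. With each tissue fitted alone the disc standard errors were 1.27 times those of extraembryonic tissue, where the group sizes alone would give 1.05. In these fits 1 disc and 72 extraembryonic probes passed. Fewer disc specimens are argued against by the 47 or more calls left without any 1 AI specimen. An effect in extraembryonic tissue only stays open. The probes called there had a median disc difference of 0.324 in the same direction (exact permutation p = 0.00433 over 462 splits). The bound written first, 0.438 (the extraembryonic size multiplied by 0.5), decided nothing. The permutation was added after the value had been seen and does not remove differences shared by numbers present in both tissues. It also moved discs singly, although some share a leading number, so its p may be too small. A relabelling of leading numbers was not run for these probes.

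The hypothesis of a shared genotype of the clones was tested by the NT to AI ratio of spreads between discs. The ratio was 0.0028 log2 units higher for called than for all probes. By the bound written first, a ratio at or above that of all probes argues against the hypothesis. A comparison with random sets of probes was not part of that bound. In it 51.74% of the sets were as low, so the called probes were not set apart and the hypothesis stays open. Among 100 splits of the specimens, the real one included, 2 had as many extraembryonic calls (highest other 85), 7 had as many disc calls (highest other 235), 100 as many for the difference (highest other 4), and 1 each between tissues in AI (highest other 5233) and in NT (highest other 4206). Chance is not excluded for the disc calls, the split test decides nothing for the difference since its real count was 0, and the many calls in some other splits point to structure among the specimens.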
